A study of Homo sapiens with 55 samples.

How the data were processed

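RNA was measured in 38 libraries of sorted skin cells, 13 of bulk skin and 4 of sorted regulatory T cells, 55 in all. Per the labels' protocols, RNA from each sample was amplified from a picogram amount of input with the Ovation RNA-seq V2 system, which primes and amplifies cDNA linearly, and the cDNA was sheared before library preparation. Amplification from so little RNA adds variation for low transcripts. The authors deposited the values as FPKM, fragments mapped to a gene scaled by transcript length and library size, in one table for the sorted populations and bulk skin and in another for regulatory T cells. Per the submitters' processing notes, the tools were FastQC 0.11.4, Trimmomatic 0.32, STAR and Cufflinks 2.2.1 with genome build hg19; the annotation, the strand setting and any scaling between libraries are not given in the sources used here. Of the non-zero deposited FPKM values, 88.8% ended in an even digit (88.6% in the regulatory T cell table), a property whose origin is not given in the sources used here.

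Each table had 26199 gene entries. Symbols of Y-linked genes, XIST, TSIX and copy-variable genes were left out (126), while other X-linked genes stayed in. This left 26073 symbols in the larger table. In the regulatory T cell table, 28 entries that held a date in place of a symbol were also not used. Positions on GRCh37, the same build as hg19, came from GENCODE v44lift37 for 23648 of these symbols. An exact 0 can be a failed estimate, because genes that every cell uses were at 0 in whole groups, so such genes are reported as listed at 0, without a fold. Near-identical copies (keratin paralogs, XCL1 and XCL2, CCL3 and CCL4 copies, CXCL1 and CXCL2) and HLA genes are uncertain, since the notes do not say how shared reads were assigned. The groups came from the sample titles. The regulatory T cell samples carry conflicting labels, as some fields name keratinocytes, and were placed by their titles and subtype.

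Read counts are not known. Where FPKM came from whole fragments, low values move in steps, and the ratio of the commonest steps between libraries, over values up to 0.5 FPKM in bins of 0.02 log2, gave each library's depth relative to the middle of its kind. This held within 0.1 log2 for 99.4% of sorted pairs and 100% of bulk pairs. All 1485 pairs of libraries were compared, 0 held identical values and the highest correlation was 0.989, so each library counted as 1 replicate.

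Tests used log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a variance trend, robust moderation and Benjamini-Hochberg adjustment. Genes entered at 1 FPKM or above in at least 8 libraries, 13070 for the 38 sorted libraries and 14896 for all 51. A call needed an adjusted p under 0.05 and a log2 fold of at least 1. The 3 contrasts between sorted populations were fitted on the 38 sorted libraries, which share one estimate of the spread, and those against bulk skin on all 51 libraries. Keratinocytes were set against the mean of the 3 immune populations, and dendritic cells against the mean of both T cell populations. A signature gene was called higher in its population than in each of the others; for the shared T cell signature, in both T cell populations than in keratinocytes and in dendritic cells. The 34 gene lists were tested by camera in limma with an estimated correlation, adjusted over lists, where at least 3 members were tested; a preset correlation of 0.01 was the alternative. Regulatory T cells were described only, as the tables may have been normalized separately. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

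Named genes followed a rule: for each main contrast up to 8 called genes per direction by fold at a mean of at least 10 FPKM on the higher side; per list up to 4 members with the smallest adjusted p in the majority direction and up to 2 the other way; always PTPRC, CD3E, CD4, CD8A, CD8B, ITGAX, HLA-DRA, CD207, KRT5, KRT14, FOXP3 and IL2RA; up to 4 per direction for the remaining bulk contrasts; the top 8 of each signature; and for regulatory T cells the top 4 by mean in 3 lists. Not every gene the rule allows is named.

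Alternatives were a pseudocount of 0.1, quantile normalization, rescaling to a sum of 1000000, no filter on low values, array weights, no fold minimum, a replicate block, a preset correlation, detection at 0.1 or 5 FPKM, and leaving out each regulatory T cell library. Chosen after seeing the data were runs without genes at 0 in every library of a group, without the 8 libraries of relative depth under 0.5, with these as a batch term, and without the 2 immune libraries with KRT14 of at least 10 FPKM. The model was tested on simulated data made from the libraries' own residuals, with 100 genes moved by 1.5 and 100 by 3 on the log2 scale in 10 simulations per contrast. Residuals were exchanged between populations, so simulated genes had the same spread in each population, as the model assumes. Genes whose spread differs between populations were not simulated, so recovery and false calls can differ for them. Recovery at 1.5 averaged 89.4% for keratinocytes against immune cells, 83.1% for dendritic cells against T cells and 64.8% for CD8 against CD4 effector cells, and at 3 it was 99.8%, 99.7% and 98.9%. The median number of unchanged genes called, of 12850, was 5, 10.5 and 6.5. Against bulk skin, recovery at 1.5 was 88.4% for keratinocytes, 88.3% for dendritic cells, 83.5% for CD8 and 84.4% for CD4 effector cells.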

Results

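Gene expression was measured by RNA sequencing in cell populations sorted by flow cytometry from surgical discards of healthy adult skin, and in pieces of whole skin. One table held 51 libraries: 11 of keratinocytes (the epithelial cells of the epidermis), 10 of dendritic cells (antigen-presenting cells), 8 of CD8 T cells, 9 of CD4 effector T cells and 13 of bulk skin. A table deposited separately held 4 libraries of regulatory T cells. The values were FPKM, so read totals are unknown, but the steps between low values gave the depth of each sorted library relative to the others, which ranged from 0.272 to 2.144. Depth among the bulk libraries ranged from 0.52 to 1.306 on a scale of their own. Under a relative depth of 0.5 lay 8 sorted libraries, of which 2 were of dendritic cells, 2 of CD8 T cells and 4 of CD4 effector T cells. Of these 8 libraries, termed shallow, 6 held the highest or second highest number of genes above 0 in their population and 2 the lowest or second lowest. The median number of genes above 0 FPKM was 13787 in keratinocytes, 12082.5 in dendritic cells, 12316 in CD8 T cells, 11973 in CD4 effector T cells, 20238 in bulk skin and 10926 in regulatory T cells. The 10 most abundant genes held a median of 20.4% of the FPKM in dendritic cells, against 11.71% in keratinocytes and 9.46% in bulk skin. Libraries of different populations can come from the same adult, since the design names 11 donors, so p-values measure the spread between libraries. Fold changes are differences of mean log2(FPKM + 1), which understate the change of low genes, with standard errors and adjusted p from limma.

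**Figure D1:**
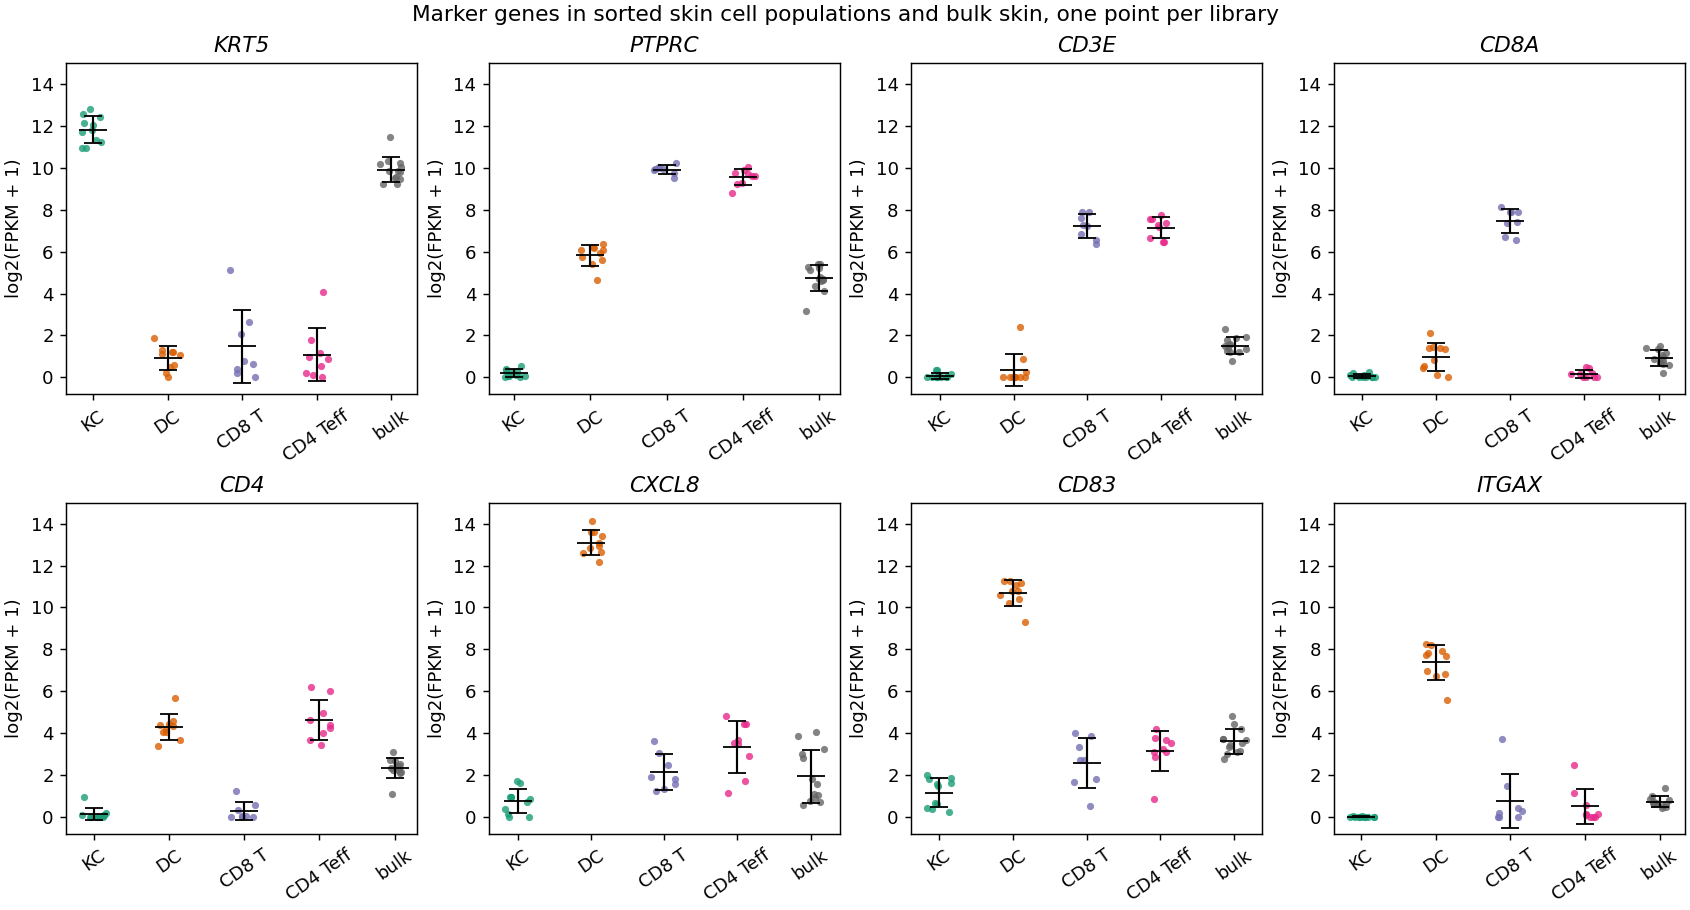
Expression of 8 marker genes as log2(FPKM + 1) (y axis) in keratinocytes (KC, n = 11), dendritic cells (DC, n = 10), CD8 T cells (n = 8), CD4 effector T cells (Teff, n = 9) and bulk skin (n = 13). Each point is a library, the black dash is the mean and the bar is 1 SD; KRT5 lay at 1967 FPKM or above in every keratinocyte library and at 34.3 or below in every immune library.

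The first comparison asked which genes separated the epithelial from the immune cells of skin. KRT5, a keratin of the basal epidermis (GRCh37 chromosome 12, start 52908359, end 52914314), stood at 3938 ± 1747 FPKM in keratinocytes (SD, n = 11) and was 10.65 ± 0.37 higher (log2 fold ± SE) than the mean of the 3 immune populations (adjusted p = 5.23e-27). KRT15 was higher by 9.12 ± 0.23, COL17A1, a hemidesmosome collagen, by 8.03 ± 0.18, the desmosomal cadherin DSG1 by 8.92 ± 0.21, and CCL27, a skin chemokine that attracts T cells, by 8.97 ± 0.28. PTPRC, the leukocyte antigen CD45 (chromosome 1, start 198607587, end 198726605), was −8.23 ± 0.14 in keratinocytes against the immune cells, and the chemokine receptor CXCR4 was −9.97 ± 0.20. CD74, the invariant chain of MHC class II, was −8.21 ± 0.24, with a mean of 2.25 FPKM in keratinocytes.

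All 14 members of the basal keratinocyte list were higher in keratinocytes, 14 also when adjusted over the list alone, with LAMA3 at 4.92 ± 0.17, and the list, with a median 4.72 above that of all genes, passed camera with an estimated correlation (adjusted p = 0.00409). Of 15 tested desmosome and cell adhesion genes, 11 were higher, 1 was lower and 3 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.00464), led by PKP1 at 7.99 ± 0.21 and CDH1 at 6.30 ± 0.18. Of 15 tested cornified envelope genes, 13 were higher and 2 lower (13 and 2 adjusted over the list alone), with DSC1 at 8.23 ± 0.24 and SPINK5 at 5.66 ± 0.29, but the list missed the threshold (adjusted p = 0.0819 with an estimated correlation). It passed without genes at 0 throughout a group (0.0374, range over alternatives 5.3e-05 to 0.13). The genes counted as lower in these lists, the suprabasal keratins KRT1 and KRT10 and the desmosomal plaque gene DSP, were listed at 0 in all 11 keratinocyte libraries. Such zeros can be failed estimates. In all, 20 genes listed at 0 in every keratinocyte library had a median of at least 100 FPKM in another group. That count can also hold genes that only other cells express, so it does not tell failed estimates from absence. All 7 tested stress keratin and antimicrobial peptide genes were higher (7 adjusted over the list alone; adjusted p = 0.0168). Of these, DEFB1 was listed at 0 in every library of both T cell populations and SLPI in every dendritic cell library.

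Melanocyte markers were also in the keratinocyte libraries: all 11 tested genes were higher than in immune cells (11 adjusted over the list alone; adjusted p = 0.0109), and the pigment enzymes TYRP1 and DCT reached 100.5 ± 30.3 and 151 ± 83.4 FPKM (SD, n = 11). Of 18 pan-T cell genes, 17 were lower in keratinocytes and 1, BCL11B, did not pass at 0.81 ± 0.15 (17 adjusted over the list alone; adjusted p = 1.29e-05). TRAT1 was −5.04 ± 0.18 and CD2 −4.75 ± 0.19. Of 17 mature dendritic cell genes, 14 were lower and 3 did not pass (14 adjusted over the list alone; adjusted p = 0.00633), with CD83 at −4.32 ± 0.29. In all, 18 of 32 lists passed camera, 4 upward and 14 downward in keratinocytes, and 0 of these 18 turned direction under either scaling. Of 13070 genes tested, 6659 passed an adjusted p of 0.05 with a log2 fold of at least 1, 4689 higher and 1970 lower in keratinocytes. Rescaling each library to a sum of 1000000 gave 5756 higher and 2181 lower, with the median over all genes at 0.747 in place of 0.501. This also raises values against the pseudocount, and a pseudocount of 0.1 by itself gave 5764 higher and 2403 lower at a median of 0.808. Quantile normalization, which makes the distributions of all libraries equal and so evens out the directions, gave 2919 higher and 2965 lower with a median of −0.028. Lists that lost their call were CD4 helper under quantile normalization (adjusted p = 0.0106, range over alternatives 0.000197 to 0.057) and type 17 and 22 helper likewise (0.0213, range 0.00968 to 0.0778). The conventional dendritic cell list lost its call without genes at 0 throughout a group (0.0109, range 0.000217 to 0.0921).

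The next comparison set dendritic cells against both T cell populations. CXCL8, a chemokine that recruits neutrophils (chromosome 4, start 74606236, end 74609433), was the most abundant of the named genes in dendritic cells at 9446 ± 4006 FPKM (SD, n = 10) and 10.36 ± 0.32 higher than in T cells (adjusted p = 4.84e-28). The lowest dendritic cell library held 4678 FPKM, and the highest T cell library 27.5. IL1B, encoding interleukin 1 beta, was higher by 8.98 ± 0.31 and INHBA, an activin subunit, by 9.15 ± 0.35. The maturation marker CD83 was higher by 7.82 ± 0.33 at 1756 ± 600 FPKM, and CCR7, the receptor that guides migration to lymph nodes, by 7.46 ± 0.33 at 1417 ± 649 FPKM. In T cells the adaptor TRAT1 was higher, with a log2 fold of −7.29 ± 0.20 for dendritic cells, followed by CD2 at −6.93 ± 0.21 and CD3E at −6.82 ± 0.23.

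Of 17 mature dendritic cell genes, 16 were higher in dendritic cells (16 adjusted over the list alone; camera with an estimated correlation, adjusted p = 7.72e-05), including LAMP3 at 7.18 ± 0.30 and CD80 at 5.13 ± 0.25. The remaining gene, the chemokine CCL22, was listed at 0 in all 10 dendritic cell libraries and above 0 in all 17 T cell libraries. Of 8 tested MHC class II genes, 7 were higher and 1 did not pass (7 adjusted over the list alone; adjusted p = 0.00596), among them CIITA, the class II transactivator, at 5.96 ± 0.29 and CD74 at 5.12 ± 0.27. HLA-DRA ranged from 1.27 to 1301 FPKM across dendritic cell libraries and is uncertain. The cause of this spread was not tested. Of 12 conventional dendritic cell genes, 11 were higher and 1 did not pass (11 adjusted over the list alone; adjusted p = 5.31e-05), with IRF8 at 5.76 ± 0.23 and SIRPA at 6.03 ± 0.25. Macrophage and monocyte genes were in the same libraries: 17 of 18 were higher and 1 did not pass (17 adjusted over the list alone; adjusted p = 5.31e-05), with LYZ at 8.23 ± 0.30, CSF1R at 5.01 ± 0.22 and the complement gene C1QC at 5.98 ± 0.27. Of 18 epithelial cytokine and chemokine genes, 14 were higher and 4 did not pass (14 adjusted over the list alone; adjusted p = 0.000562). CXCL8, IL1B, CXCL2 at 8.28 ± 0.36 and CXCL1 at 8.13 ± 0.43 led it, which myeloid cells also make. CXCL1 and CXCL2 are close paralogs whose split is uncertain.

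Of 6 tested Langerhans cell markers, 4 were higher and 2 did not pass (4 adjusted over the list alone), with CD1E at 3.84 ± 0.25 and CD207, the langerin gene, at 1.76 ± 0.36. The list passed with an adjusted p of 0.0235, which became 0.0735 without the shallow libraries, 0.0645 without genes at 0 throughout a group and 0.0555 with the replicate block (range over alternatives 0.00486 to 0.0735). Of 18 pan-T cell genes, 17 were lower in dendritic cells and 1 did not pass (17 adjusted over the list alone; adjusted p = 1.98e-07). In all, 7 of 32 lists passed, 6 upward and 1 downward, and 0 turned direction under either scaling. Of 13070 genes, 4392 passed, 1961 higher in dendritic cells and 2431 lower. The median over all genes was −0.18, and −0.302 after rescaling to equal sums.

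CD8 and CD4 effector T cells were compared directly to find what separates the main T cell populations of skin. KLRK1, the activating receptor NKG2D, differed most, at 442 ± 96.4 FPKM in CD8 T cells (SD, n = 8) and at or below 1.69 FPKM in the 9 CD4 effector libraries, a log2 fold of 8.19 ± 0.32 (limma adjusted p = 3.74e-23). CD8A (chromosome 2, start 87011733, end 87035519) was higher in CD8 T cells by 7.32 ± 0.25 and CD8B by 6.66 ± 0.28, while CD4 (chromosome 12, start 6896024, end 6929965) was −4.33 ± 0.31, at 29.4 ± 22.7 FPKM in CD4 effector cells. GNLY (granulysin) was higher in CD8 T cells by 5.03 ± 0.57 and GZMB (granzyme B) by 4.60 ± 0.47. The inhibitory receptor CTLA4 was −2.17 ± 0.32, higher in CD4 effector cells. CD3E (0.07 ± 0.28) and PTPRC (0.35 ± 0.19) did not pass.

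Of 21 CD8 and cytotoxic effector genes, 18 were higher in CD8 T cells and 3 did not pass (20 higher adjusted over the list alone; camera with an estimated correlation, adjusted p = 9.9e-10), among them CRTAM at 4.47 ± 0.36. The NK cell list passed (adjusted p = 1.58e-05) on 2 of 5 genes, 2 also adjusted over the list alone: the chemokines XCL1 at 4.85 ± 0.50 and XCL2 at 5.35 ± 0.50, near-identical copies whose separate values are uncertain. Of 14 CD4 helper genes, 6 were lower in CD8 T cells and 8 did not pass (8 lower adjusted over the list alone; adjusted p = 7.04e-07), with TNFRSF25 at −1.90 ± 0.34, ZBTB7B, a regulator of CD4 lineage choice, at −1.67 ± 0.32 and CCR4 at −1.75 ± 0.37. Of 8 type 17 and 22 helper genes, 5 were lower in CD8 T cells and 3 did not pass (5 adjusted over the list alone; adjusted p = 3.16e-08), with KLRB1 at −2.21 ± 0.39 and RORA at −1.17 ± 0.25. The tissue residency list passed (adjusted p = 0.00285) with 1 of 12 genes past the threshold, ZNF683 (the transcription factor HOBIT) at 4.03 ± 0.37, 1 also adjusted over the list alone. Its adjusted p was 0.284 without the shallow libraries (range over alternatives 0.00121 to 0.284). Type 1 helper genes did not pass as a list (adjusted p = 0.388), with 2 of 10 higher, IFNG at 2.45 ± 0.50 and TBX21 at 1.61 ± 0.38, 2 also adjusted over the list alone. The regulatory T cell list did not pass (adjusted p = 0.373), with 2 genes higher, 1 lower and 14 not passing (3 and 5 adjusted over the list alone). It passed without genes at 0 throughout a group (0.0413, range over alternatives 0.0413 to 0.603). FOXP3 reached at most 10.8 FPKM in CD4 effector cells and did not pass at −1.19 ± 0.44.

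**Figure D2:**
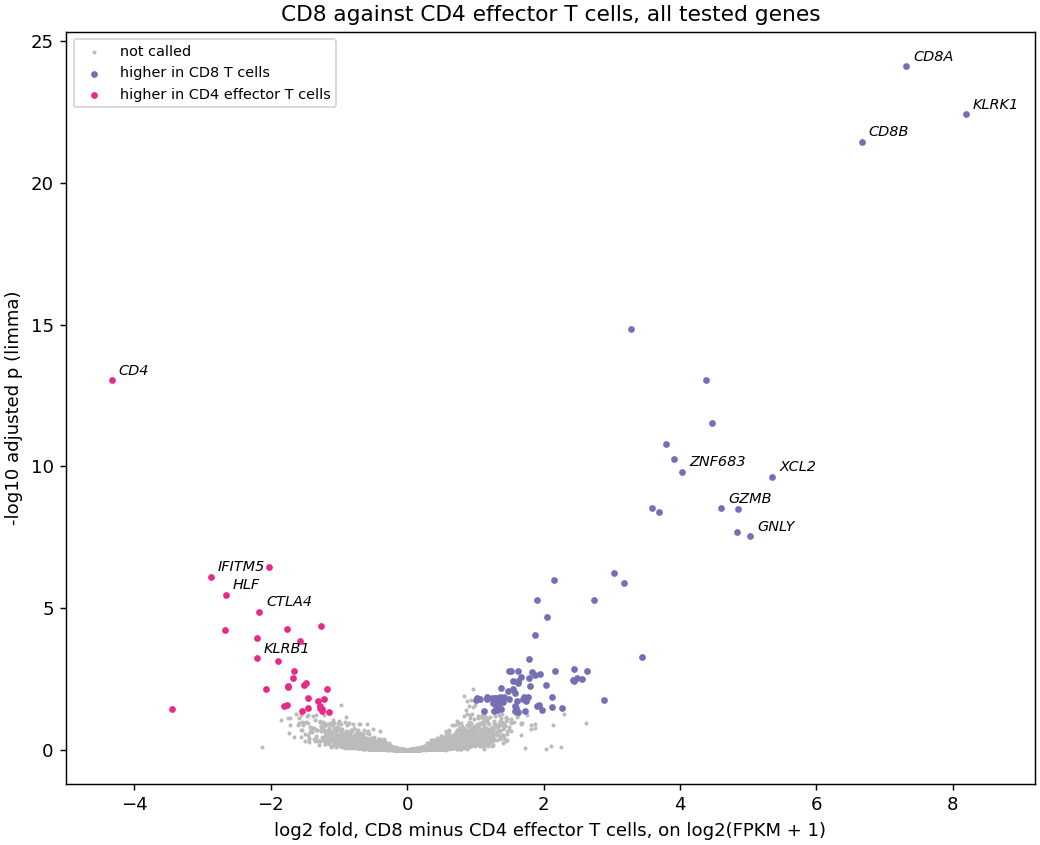
All 13070 tested genes in CD8 (n = 8) against CD4 effector T cells (n = 9): log2 fold on log2(FPKM + 1) (x axis) against −log10 adjusted p from limma (y axis). Purple points are the 91 genes called higher in CD8 T cells, pink points the 33 called higher in CD4 effector T cells and grey points all others.

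Of the 13070 genes, 124 passed, 91 higher in CD8 T cells and 33 higher in CD4 effector cells. The count was 73 without the 8 shallow sorted libraries, an alternative chosen after seeing the data. In 2 CD8 libraries KRT14 reached at least 10 FPKM, a level of keratinocyte RNA, and 98 genes passed without them, with fewer libraries in the fit. In CD4 effector libraries KRT14 reached at most 6.98 FPKM, but KRT5 reached 15.7 and KRTDAP 104.67 FPKM. The KRT14 bound can therefore miss keratinocyte RNA.

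**Figure D3:**
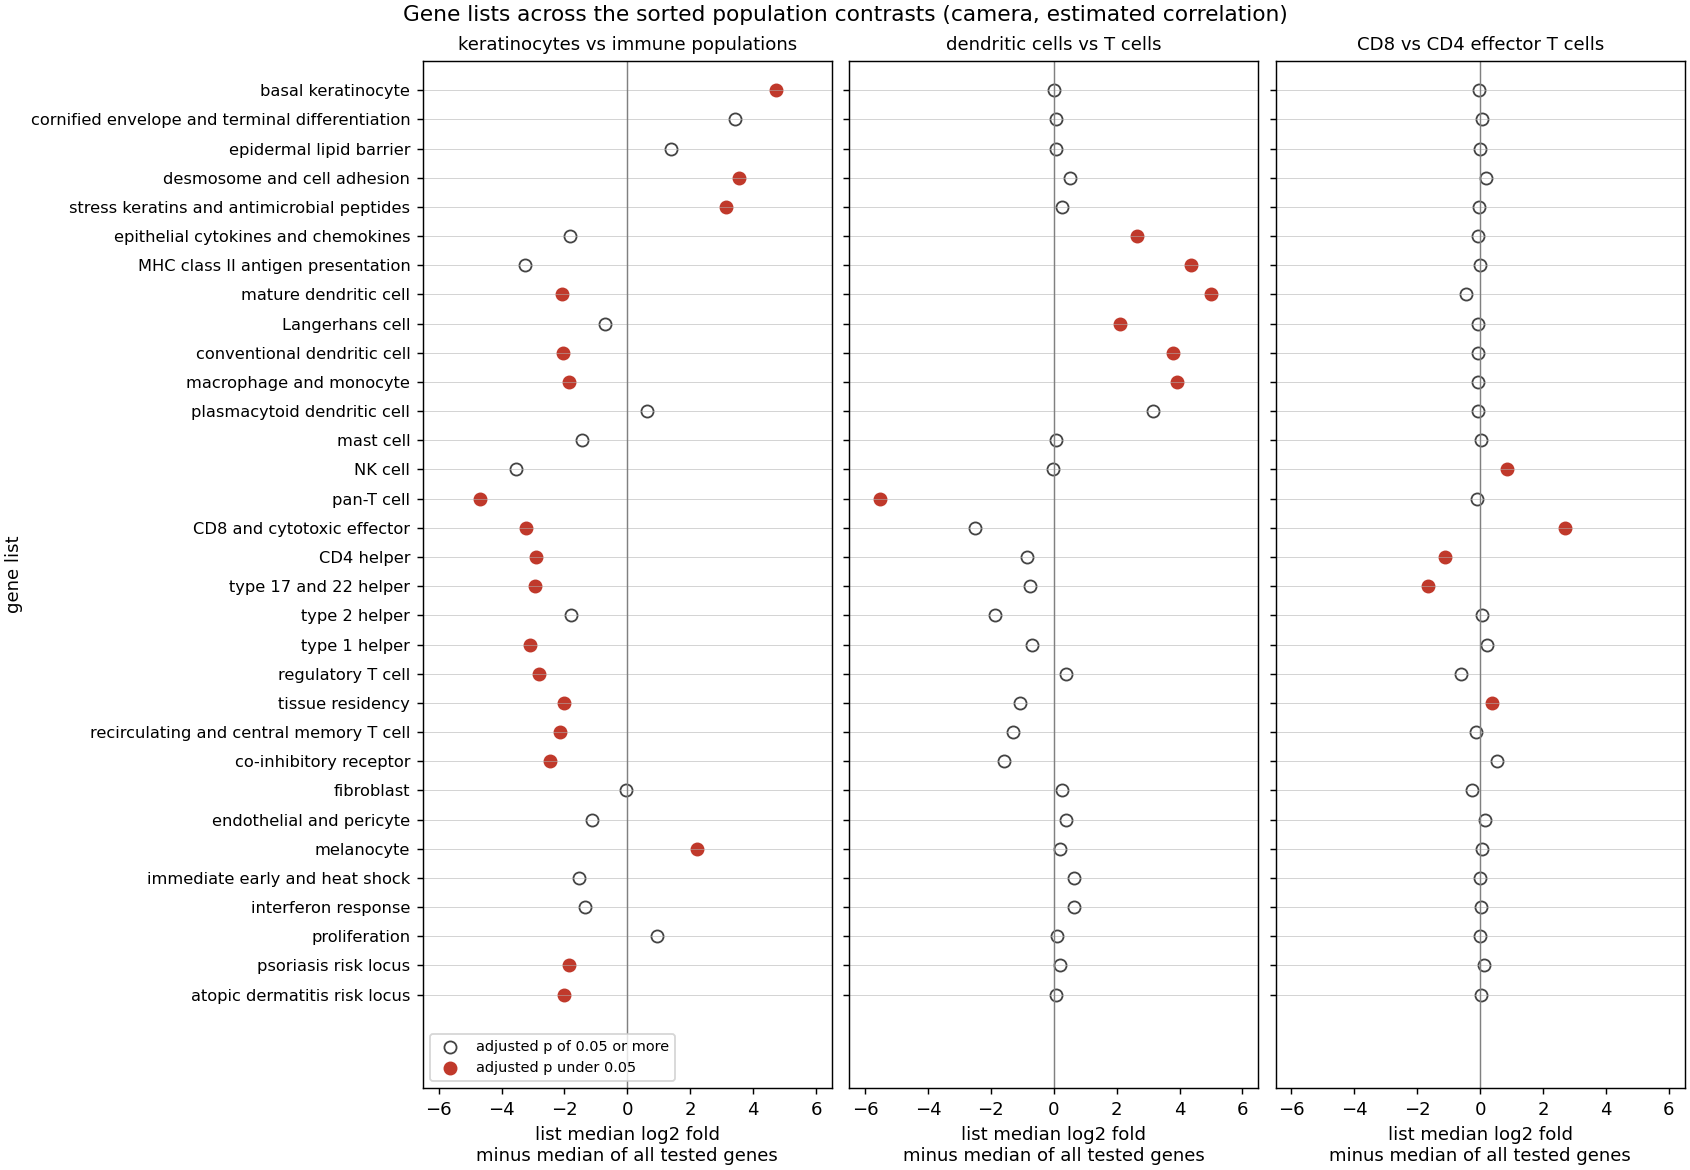
Median log2 fold of each of 32 gene lists minus the median of all tested genes (x axis) in the 3 contrasts between sorted populations. Red points had an adjusted p under 0.05 by camera with an estimated correlation (18, 7 and 5 lists from left to right) and white points did not.

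Signatures were the genes higher in a population than in each of the others. The keratinocyte signature held 3300 genes, whose named members, ranked by the smallest of their pairwise folds, were MALAT1, KRT14, KRT5 at 10.32, DMKN, KRTDAP, KRT15, LY6D and DSG1. MALAT1, a nuclear long noncoding RNA, was listed at 0 in every immune library and in all 13 bulk libraries. Such zeros can be failed estimates, so its rank as a keratinocyte gene is uncertain. Without genes at 0 throughout a group, the keratinocyte signature held 3057 genes. The dendritic cell signature held 1078 genes, with CXCL8 at 9.74 followed by INHBA, TYROBP, IL1B and EREG, an epidermal growth factor receptor ligand. Shared by both T cell populations were 738 genes, with TRAT1 at 7.28, CD3E at 6.79, and CD2, THEMIS, SPOCK2, CD96 and CD28. The CD8 signature held 44 genes, led by KLRK1 at 7.89 and CD8B, CD8A, GNLY and NKG7. The CD4 effector signature held 17 genes, with IFITM5 at 2.88, KLRB1 at 2.21, CTLA4 at 2.17, MCAM at 1.76 and CCR4 at 1.75. It fell to 7 genes with a pseudocount of 0.1 and to 9 without the shallow libraries, and the CD8 signature to 27 without the shallow libraries. The keratinocyte signature fell to 1983 genes under quantile normalization.

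Each sorted population was then compared with bulk skin, whose libraries were first deposited with another study, so that the batch and the tissue cannot be told apart. Keratinocytes held more KRT5 than bulk skin by 1.91 ± 0.38, with 1050 ± 577 FPKM in bulk (SD, n = 13), more COL17A1 by 1.99 ± 0.22 and more of the integrin gene ITGB4 by 2.04 ± 0.21. They held less of the collagen gene COL3A1 by −7.15 ± 0.29, of MGP, a matrix protein gene, by −7.44 ± 0.31 and of the calprotectin subunit S100A9 by −9.01 ± 0.43. LUM, a dermal proteoglycan gene at 129 ± 58.1 FPKM in bulk, and DCD, a sweat gland peptide gene, were listed at 0 in all 11 keratinocyte libraries. KRT14, EEF1A1, MALAT1, DSG1, DST, AHNAK and TXNIP were listed at 0 in all 13 bulk libraries, and no fold is given for them.

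Of 14 basal keratinocyte genes, 12 were higher in keratinocytes than in bulk and 2 did not pass (12 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.0176, with 0.0644 under quantile normalization in a range of 6.54e-10 to 0.0644 over alternatives). Of the 12, KRT14 and DST were listed at 0 in bulk. Of 24 cornified envelope genes, 15 were lower, 5 higher and 4 did not pass (15 and 5 adjusted over the list alone; adjusted p = 0.628), with IVL at −4.37 ± 0.30 and TGM1 at −3.43 ± 0.26, and KRT1 listed at 0 in keratinocytes; of the 5 higher genes, DSG1 and FLG were listed at 0 in bulk. Of 15 stress keratin and antimicrobial peptide genes, 14 were lower and 1 did not pass (14 adjusted over the list alone; adjusted p = 0.0178), with KRT6A at −5.15 ± 0.29 and KRT6B at −6.06 ± 0.29, close paralogs whose split is uncertain. Fibroblast genes were lower in 16 of 18, with 1 higher and 1 not passing (16 and 1 adjusted over the list alone; adjusted p = 0.0365). This p became 0.0517 without the libraries holding keratinocyte RNA and 0.121 without genes at 0 throughout a group (range over alternatives 1.98e-10 to 0.121). The higher gene was POSTN (periostin) at 1.26 ± 0.34. Of 18 endothelial and pericyte genes, 17 were lower and 1, NOTCH3, was higher at 3.02 ± 0.24 (17 and 1 adjusted over the list alone; adjusted p = 0.0176), with KDR at −2.68 ± 0.17 and VWF at −2.92 ± 0.21. Sweat gland, hair follicle and adipocyte genes were lower in 17 of 18, with 1 not passing (17 adjusted over the list alone; adjusted p = 0.0136), including KRT19 at −4.92 ± 0.22. That p was 0.0787 without genes at 0 throughout a group (range over alternatives 7.34e-12 to 0.0787). Langerhans cell genes were lower in 6 of 7 with 1 not passing (6 adjusted over the list alone), with CD207 at −3.85 ± 0.36. The adjusted p of this list was 0.0463, and the call was lost under 5 of 8 alternatives (range 0.0175 to 0.0787): a pseudocount of 0.1, quantile normalization, and leaving out the shallow libraries, those with keratinocyte RNA or genes at 0 throughout a group. Of 14896 genes tested against bulk, 6063 passed in keratinocytes, 1596 higher and 4467 lower. With equal sums there were 1784 higher and 5455 lower genes at a median over all genes of −0.584 in place of −0.443, and a pseudocount of 0.1 gave 1684 and 5765 at −0.708. With quantile normalization there were 2825 higher and 2755 lower at a median of 0.069.

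Dendritic cells held more CXCL8 than bulk skin by 11.15 ± 0.39, more CCR7 by 9.05 ± 0.32 and more ITGAX, the integrin CD11c, by 6.65 ± 0.30, and less KRT5 by −8.99 ± 0.39 and S100A8 by −9.48 ± 0.49. CD207 was −2.04 ± 0.37, lower in the sorted dendritic cells than in whole skin. Of 17 mature dendritic cell genes, 16 were higher than in bulk and 1, CCL22, listed at 0 in dendritic cells, counted as lower (16 and 1 adjusted over the list alone; camera with an estimated correlation, adjusted p = 0.000182). CD3E was −1.17 ± 0.22 against bulk but 0.12 after quantile normalization. CD8 T cells exceeded bulk in CD3E by 5.69 ± 0.24 and CD8A by 6.55 ± 0.21, and CD4 effector cells in CD3E by 5.62 ± 0.23 and CD4 by 2.28 ± 0.26. S100A9 was listed at 0 in all 8 CD8 and all 9 CD4 effector libraries. All 18 pan-T cell genes were higher than in bulk in CD8 T cells (adjusted p = 5.62e-06) and in CD4 effector cells (adjusted p = 4.48e-06), 18 in each also adjusted over the list alone.

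Against bulk, 9446 genes passed in dendritic cells (1821 higher, 7625 lower), 8935 in CD8 T cells (1890 higher, 7045 lower) and 9307 in CD4 effector cells (1922 higher, 7385 lower). The medians over all genes were −1.049, −0.90 and −0.988, and −1.575, −1.33 and −1.40 with equal sums. Equal sums gave 1760 higher and 9072 lower genes in dendritic cells, 1910 and 8305 in CD8 T cells and 2006 and 8533 in CD4 effector cells, and a pseudocount of 0.1 gave 1905 and 9109, 1982 and 8410, and 2035 and 8706. Quantile normalization, which evens out the directions, gave 3676 and 3795, 3823 and 3636, and 3904 and 3795. The lists passing numbered 11, 16 and 16 of 34, and without the shallow libraries the dendritic cell count was 7. Relative to the median of all genes, 0 of these lists turned direction under either scaling.

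Signature genes were looked up in bulk skin to see how many are detected there. The signatures were defined among the sorted populations only, so cells that were not sorted can also supply these transcripts. Bulk libraries held a median of 13298 genes at 1 FPKM or above, and the share detected over all tested genes was not computed. Detection therefore does not show that whole tissue registers a given population. At a median of at least 1 FPKM in bulk stood 3160 of 3300 keratinocyte signature genes (95.8%), 881 of 1078 dendritic cell genes (81.7%), 588 of 738 shared T cell genes (79.7%), 13 of 17 CD4 effector genes (76.5%) and 20 of 44 CD8 genes (45.5%). The median level of the keratinocyte signature was 9.96 FPKM in keratinocytes and 9.62 in bulk, whereas the CD8 signature stood at 23.1 FPKM in CD8 T cells and 0.654 in bulk. KLRK1 had a median of 2.14 FPKM in bulk, CXCL8 1.98 and KRT5 909.7. With a threshold of 5 FPKM, 544 dendritic cell, 358 shared T cell, 6 CD8 and 5 CD4 effector genes were detected. With a threshold of 0.1 FPKM these were 1051, 723, 40 (90.9%) and 15, so the low share of the CD8 signature holds for the higher thresholds.

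The 4 regulatory T cell libraries were described without a test, since their table was deposited apart from the others. Some of their labels name keratinocytes, while the titles and cell subtype name regulatory T cells. FOXP3, the lineage transcription factor of regulatory T cells (chromosome X, start 49106899, end 49121262), stood at 39.6, 258, 436 and 623 FPKM, between the 95.2 and 99.5 percentiles of all genes in their libraries. IL2RA, the interleukin 2 receptor alpha chain, was at 229 ± 81.2 FPKM (SD, n = 4), CTLA4 at 347 ± 100.8 and BATF at 373 ± 169. CD3E ranged from 149 to 620 FPKM and CD4 from 41.5 to 334. CD8B and HLA-DRA were listed at 0 in all 4 libraries. The median percentile of the regulatory T cell list lay between 95.1 and 98.0 across libraries, with 15 of 17 genes at 1 FPKM or above in each, and that of the pan-T cell list between 96.9 and 97.9, with 17 of 18. Basal keratinocyte genes had median percentiles of 49.9 to 75.9, with 0 of 14 at 1 FPKM or above in each library. KRT5 was below 0.344 FPKM in 3 libraries and at 123 in 1, and KRT14 ranged from 0 to 8.84.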

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

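The tests of random splits and removals, and both tests of whether the zeros are absent transcripts, were chosen after their results were seen; the other tests were set before. The values tested for a library far from the rest of its group were 98 sets, each a gene or a library measure in a population, and 16 showed one. Keratinocytes and bulk skin were not tested, as the test covered smaller groups only. Chance flags about 1 in 20 groups of normally distributed values, and these sets overlap in libraries. Some of the sets hold mostly zeros, for which that share need not apply. The number given is the gap to the nearest library divided by the range of the group. In dendritic cells it was 0.638 for CD3E, 0.485 for CD4, 0.699 for CD8B and 0.589 for FOXP3. In CD8 T cells it was 0.533 for CD4, 0.603 for ITGAX, 0.774 for HLA-DRA, 0.695 for CD207 and 0.761 for FOXP3. In CD4 effector T cells it was 0.543 for ITGAX, 0.624 for CD207 and 0.556 for KRT5. In regulatory T cells it was 1 for CD8A and for CD207, 0.957 for KRT5 and 0.845 for KRT14. The value of 1 follows from zeros in 3 of 4 libraries, with CD8A at 0.21 and CD207 at 0.718 FPKM in the remaining one.

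Of the 1781 genes with a median of at least 10 FPKM in each sorted population, 6 were listed at 0 in all 13 bulk libraries, among them EEF1A1, AHNAK, TXNIP, PDE4DIP and NOTCH2NL. That the transcripts are absent from whole skin was argued against for EEF1A1 and AHNAK, whose lowest population medians of 1298 and 206 FPKM were above the bound of 100. The count of 6 left the question open for the others. Abundant loci left without an estimate are a candidate explanation: 1.2% of the 168 genes highest in FPKM times transcript length were at 0 (2 genes) against 0 of the 839 lowest (one-sided permutation p = 0.028), though this rests on 2 genes. Sorted populations had genes at 0 in every library and at a median of 100 FPKM or more in another group as well. There were 20 in keratinocytes, 15 in dendritic cells, 21 in CD8 T cells and 15 in CD4 effector cells, against 9 in bulk skin. In a sorted population such a gene can belong to another cell type, so these counts do not show failed estimates. No biological explanation was tested.

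Without the 8 shallow libraries, CD8 against CD4 effector cells gave 73 genes in place of 124. A smaller number of libraries is a candidate explanation: of 99 random removals of as many libraries per population, 53 gave 73 genes or fewer, with a median of 69 and a range of 35 to 142. Keeping all libraries with the shallow ones as a batch term gave 142 genes. An effect of depth itself, or of another property of these libraries, stays open, since 4 of the 8 were of CD4 effector cells. Low depth predicts few genes above 0, and 2 of the 8, both of CD4 effector cells, held the lowest or second lowest number in their population. The other 6 held the highest or second highest number in theirs, against that prediction. The term shallow therefore names the relative depth only.

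Macrophage genes such as LYZ, CSF1R and C1QC were high in the dendritic cell libraries. That a few libraries carried the macrophage list as a whole was argued against. Its mean lay above the highest T cell library (0.79 log2) in 10 of 10 dendritic cell libraries, from 3.24 to 5.08. Members that dendritic cells express can raise this mean too. The test therefore cannot say whether the remaining members came from a few libraries. A varying share of macrophages among the sorted cells may contribute: the 18 genes had a mean pairwise correlation of 0.13 across the dendritic cell libraries, above 99.6% of 1000 lists matched on expression (median −0.003). Dendritic cells also express several of these genes, LYZ and CSF1R among them, which stays open as a biological explanation.

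Chance was tested with 99 other splits of the same libraries per contrast, and in each of the 12 results only the real split, 1 of 100 drawn, reached the real value. For the CD4 effector signature an earlier draw, since replaced, also held another split as large, so chance stays possible there. The splits compare numbers of genes and do not show which genes are real. A chance split was argued against for keratinocytes against immune cells (6659 genes, highest other 1991), dendritic cells against T cells (4392, highest other 1889) and CD8 against CD4 effector cells (124, highest other 72). It was argued against for the signatures of keratinocytes (3300, highest other 2), dendritic cells (1078, highest other 0), both T cell populations (738, highest other 0) and CD8 T cells (44, highest other 31). In the kept draw the CD4 effector signature had 17 genes against a highest other of 14. Against bulk skin a chance split was argued against for keratinocytes (6063, highest other 2418), dendritic cells (9446, highest other 6580), CD8 T cells (8935, highest other 5752) and CD4 effector T cells (9307, highest other 6543), where batch and tissue cannot be told apart.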

How the results depend on the processing

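Leaving out shallow libraries, keratinocyte RNA libraries or genes at 0 throughout a group, and the shallow batch term, were chosen after seeing the data, as were the sum rescaling and block for lists; the rest were set before the data were examined. Of the main counts under each alternative, 196 stayed within 1.5 times, 5 rose and 10 fell beyond it. The 196 include 4 FOXP3 means of regulatory T cells, judged by SD. For named genes and lists, 3426 kept their status as called or not called, 93 gained a call and 82 lost it. Direction was not compared where neither run gave a call, and 12 of the 3426 are regulatory T cell means without a call. A reversal was counted for 1, CD3E in dendritic cells against bulk skin, 0.12 with quantile normalization (main −1.17). The cause was not tested except where given.

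The CD4 effector signature fell from 17 to 7 genes with a pseudocount of 0.1, and the keratinocyte signature from 3300 to 1983 with quantile normalization. Dropping the fold minimum raised keratinocytes against bulk skin to 9209, by construction. Without the shallow libraries, with fewer libraries in the fit, CD8 against CD4 effector cells gave 73, the CD8 signature 27, the CD4 effector signature 9, and dendritic cells against bulk skin 7 lists in place of 11. The preset correlation raised the lists that passed from 79 to 122 in all, from 6 to 11 for keratinocytes and from 11 to 23 for dendritic cells against bulk skin; all 79 also passed with it. Detection at 5 FPKM, a stricter bound, left 544 dendritic cell, 6 CD8, 5 CD4 effector and 358 shared T cell signature genes in bulk skin, and at 0.1 FPKM 40 CD8 genes.

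Replicate numbers showed no pairing of the sorted libraries by correlation: 51 pairs with the same number had correlations of −0.11 to 0.16, 2 above 0.1. Of 37 libraries, 6 correlated best with their own number. This cannot show whether equal numbers name the same adult, since HLA, Y-linked and copy-variable genes and XIST, which differ between people, were left out. With the replicate block the counts were 6663, 4378 and 97 for the 3 sorted contrasts, signatures 3247, 1064, 40, 15 and 722, and 20, 6 and 5 lists passed. Leaving out 1 regulatory T cell library at a time moved the FOXP3 mean from 339 FPKM to between 245 and 439 FPKM. With 4 libraries such a mean cannot move by 1 SD whatever the values, so the SD bound tested nothing. Unknown read totals limit what can be said of genes near 0.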

Other observations

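The list tests given here were planned, except that some of the alternatives behind the ranges were chosen after seeing the data. Immediate early genes, induced within minutes of stress, and heat shock genes were in part higher in sorted cells than in bulk skin: 10 of 20 in keratinocytes with 1 lower, 14 in dendritic cells with 1 lower, and 12 in each T cell population with 1 lower. EGR1 in keratinocytes was 4.57 ± 0.35 above bulk, at 1283 ± 995 against 48.9 ± 28.6 FPKM (SD, n = 11 and 13), IER2 3.13 ± 0.26 and FOSB 4.06 ± 0.42, whereas NR4A2 was −1.02 ± 0.34. Camera with an estimated correlation gave adjusted p of 0.264, 0.0473, 0.0611 and 0.0562 for keratinocytes, dendritic cells, CD8 and CD4 effector cells, each in turn. The ranges over alternatives were 1.59e-05 to 0.447, 1.01e-08 to 0.204, 3.83e-07 to 0.24 and 5.12e-07 to 0.228, with the upper ends from quantile normalization and the lower ends from the preset correlation. Between sorted populations it did not pass, with adjusted p of 0.436 for keratinocytes against immune cells, 0.855 for dendritic cells against T cells and 0.986 for CD8 against CD4 effector cells.

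Proliferation genes were higher in keratinocytes than in immune cells in 17 of 20, with 3 not passing (17 adjusted over the list alone), among them TOP2A, a cell cycle topoisomerase, at 2.42 ± 0.26 and RRM2 at 2.54 ± 0.27; the list missed the threshold (camera, adjusted p = 0.0902 with an estimated correlation, range over alternatives 0.00479 to 0.122). Genes at psoriasis risk loci, 26 tested, were lower in keratinocytes than in immune cells in 14 and higher in 6 (adjusted p = 0.0053), and of 23 at atopic dermatitis risk loci 14 were lower and 3 higher (adjusted p = 0.000419). In dendritic cells against T cells these lists had adjusted p of 0.534 and 0.782, and in CD8 against CD4 effector cells 0.933 and 0.582. Interferon response genes did not pass in any of the 3 sorted contrasts (adjusted p = 0.289, 0.759 and 0.933), with a range over alternatives of 0.0102, from the preset correlation, to 0.37 in the first.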
